A study of Mus musculus with 20 samples.

How the data were processed

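The series holds 20 Affymetrix mouse arrays of sorted Treg cells in 7 groups, grouped by the inhibitor and time that the labels give. Per the labels' protocols, RNA was extracted with RNeasy Micro and amplified from 1 to 20 ng with NuGEN WTA Pico v2 and labelled with Encore Biotin. Per the submitters' processing notes, the authors normalized the arrays with RMA in Affymetrix Expression Console 1.1, and the deposited values are on the log2 scale. RMA corrects background, sets all arrays to 1 distribution and summarizes probes into probe sets. The 2 deposited tables of the same arrays differed by at most 1.8e-15, so 1 was used and the alternative of taking the other was not run. No 2 arrays were copies of each other, since the smallest mean absolute difference between any 2 was 0.169 on the log2 scale.

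The table has 28846 probe sets, of which 22206 measure genes and the others are controls (31 AFFX, 63 ERCC, 5222 negative and 1324 positive). Of the gene probe sets 22202 have 1 gene symbol, 1 has several and 3 have none, and the last 4 were left out. Accessions matched a mouse reference table for 20468 probe sets, which updated 911 symbols and gave 21928 symbols, 180 of them with several probe sets. A probe set was kept when its value was above that array's median over all probe sets on at least 2 arrays, and each symbol was represented by the probe set with the highest mean over all arrays, which left 12462 genes. Signal over background limits what dim genes can show. Each named gene was compared with the negative controls: where its mean in a group was at or below the mean of that group's negative-control medians, the size of the change is called limited by background. Single negative controls spread widely around that median, so it is not the background of each probe set. The arrays' separate background probes averaged lower, 4.14 to 4.411 per array against negative-control medians of 4.937 to 5.666. The rule may therefore call some genes limited that lie above their own background. Genome coordinates were not used here.

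Gene tests used limma 3.58.1 in R 4.3.3 with a mean for each of the 7 groups on all 20 arrays, moderated variances without trend or robust settings (13 residual and 4.98 prior degrees of freedom, median residual SD 0.136 on the log2 scale), 2-sided tests and Benjamini-Hochberg adjustment within each comparison at 0.05. The 11 comparisons were 3 of time within DMSO, 4 of an inhibitor with DMSO of the same time, 2 of GGTI with FTI, and 2 interactions of inhibitor and time. Values after ± are standard errors of the log2 fold change unless named as SD. "At least 2-fold" means an adjusted p under 0.05 with an absolute log2 fold change of 1 or more. With 2 arrays in GGTI_18h, the variance of that group rests largely on the other groups.

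Before the data were examined, 30 gene lists with 603 entries were fixed from general knowledge, of which 5 entries have no probe set (Tm7sf2, Acsl3, Ighm, Hbb-b1 and Hbb-b2). They include effector Treg, resting and naive T cell, Treg identity, TCR and NF-kappaB induced, ERK pathway output, sterol synthesis, fatty acid synthesis, glycolysis, amino acid transporter, ATF4 stress, DNA replication, mitosis, ribosome biogenesis, oxidative phosphorylation, interferon response, p53 target, BCL2 family, prenylation machinery, Ras and Rap family GTPase, SRF and actin cytoskeleton, T cell cytokine, IL-2 and STAT5 induced, NRF2 target, lysosome and autophagy, and heat shock genes, and markers of B cells, myeloid and dendritic cells, CD8 T and NK cells, and red cells. Lists with at least 5 measured genes were tested with limma's camera, which asks whether a list moved relative to all other genes, with its preset correlation between genes of 0.01 and beside it with the correlation estimated for each list, adjusting over the lists of a comparison. Where 2 adjusted p stand together after 1 list, the first uses the preset and the second the estimated correlation. Counts of list members use the adjustment over all genes, and "adjusted over the list alone" repeats it among the list's own genes.

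The genes named in the text follow a rule that was fixed with the lists. Between groups these are the 8 largest and 8 smallest changes among called genes whose arrays do not overlap between the groups, leaving out unnamed gene models, small RNAs and receptor segments, and up to 4 members with the smallest p of each list described. For interactions the 5 smallest p in each direction were taken. A fixed set was always available, which included Foxp3, Il2ra, Icos, Ctla4, Tigit, Irf4, Myc, Mki67, Nr4a1, Klf2, Rhob, Fntb, Fnta and Pggt1b.

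Inhibitor effects on stimulation genes were summarized as the mean effect signed by the direction of stimulation, with the genes taken from a DMSO comparison that shares no array with the inhibitor's, and tested by exact permutation of the arrays. The calls shared by both inhibitors were compared with the number for independent lists and with 100 simulated draws in which unchanged groups share the same controls.

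The tests were tested on simulated data with the spread and group sizes of the arrays. Genes were drawn independently of each other, so the camera results of the simulation do not cover lists of correlated genes. In a simulation of FTI_18h against DMSO_18h with 12462 genes, 71.6%, 97.0% and 100% of genes changed by log2 0.5, 1 and 2 were called, 6.63% of calls fell on unchanged genes, and camera called 1 list shifted by 0.3 and 1 of the unshifted lists. For GGTI_18h these were 62.7%, 95.5% and 100%, 6.88%, 1 and 0.

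The alternatives tried were no filter on dim probe sets and a stricter one at the 65th percentile, the mean of a gene's probe sets, quantile normalization repeated, arrays centred on their median, variances with trend and robust settings, array quality weights, a fit on only the arrays compared, the 2-fold threshold, the estimated correlation, and each array left out in turn. A further one, chosen after seeing the data, left out DMSO_18h replicate 3 and DMSO_0h replicate 2 together. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and array weights used statmod 1.5.0.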

Results

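Gene expression was measured on 20 arrays of mouse regulatory T (Treg) cells, the CD4 T cells that restrain immune responses and are marked by the transcription factor Foxp3. The cells were YFP-positive CD4 cells, which the labels call cTreg, sorted from spleen and lymph nodes of C57BL/6J mice that carry a YFP-Cre reporter in Foxp3. The labels name no stimulation for DMSO_0h. All other groups were stimulated in culture for 18 or 48 h with antibodies to CD3 and CD28 at 10 ug/ml and interleukin-2 at 200 U/ml, labelled DMSO or with 1 of 2 prenylation inhibitors that the labels call FTI and GGTI. The labels give the inhibitor arrays 2 h of inhibitor before stimulation and name no such step for DMSO. Prenylation attaches a farnesyl or geranylgeranyl lipid to proteins such as the small GTPases. The groups were DMSO_0h, DMSO_18h, FTI_18h, DMSO_48h, FTI_48h and GGTI_48h with 3 arrays each, and GGTI_18h with 2 arrays. The inhibitors' compound names and doses are not given in the sources used here. The labels do not say whether replicates are separate mice, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

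The arrays separated by time and by inhibitor. The first principal component, 59.6% of the variance, set DMSO_0h apart from the stimulated groups, and the second, 16.2%, set GGTI_48h apart from the other 48 h groups. Within groups the arrays correlated at r = 0.9785 to 0.9943 across genes, which are not independent replicates. DMSO_18h replicate 3 had the highest reading on the background probes richest in G and C, 6.989 on the log2 scale against 6.306 to 6.794 on the other arrays. The 3 DMSO_0h arrays had higher negative-control medians (5.583 to 5.666) than the other arrays (4.937 to 5.32). The mean over all background probes showed no such rise, at 4.146 to 4.205 on the DMSO_0h arrays and 4.14 to 4.411 on the others. The quality weights of limma were lowest for DMSO_0h replicate 2 (0.344) and DMSO_18h replicate 3 (0.434).

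**Figure D1:**
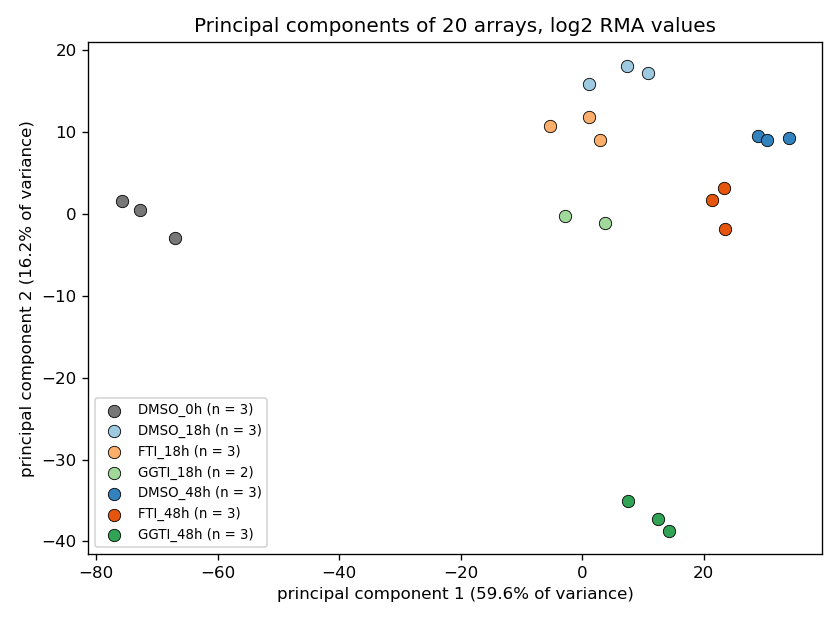
Each point is 1 array, placed by its scores on principal component 1 (59.6% of variance, horizontal) and 2 (16.2%, vertical) of the log2 values, and colours mark the 7 groups. The 3 DMSO_0h arrays lie between -75.8 and -67 on component 1, and the 3 GGTI_48h arrays between -38.7 and -35 on component 2.

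The DMSO arrays show what changed in stimulated culture without an inhibitor. No group was kept for 18 or 48 h without stimulation. Effects of time in culture, interleukin-2 and the antibodies therefore cannot be told apart, and stimulation here stands for all of them together. By 18 h genes of DNA replication and ribosome production had risen. Dctd (deoxycytidylate deaminase), Cdk1 (the main mitotic kinase), Bcat1 (a branched-chain aminotransferase) and Hk2 (hexokinase) rose by log2 4.44 ± 0.11 (SE), 4.35 ± 0.21, 4.22 ± 0.092 and 4.11 ± 0.28, and Gins1, Pbk, Exo1 and Fignl1 rose by 3.87 to 4.11. Ramp3, the G protein regulator Rgs2 and the chemokine receptor Cxcr4 fell, at log2 -4.46 ± 0.16, -4.05 ± 0.15 and -4.05 ± 0.17, and Pou6f1, Vps37b, Il1rl1 and the early response gene Fosb fell, at log2 -3.40, -3.24, -3.13 and -3.08. Il2ra, the high-affinity interleukin-2 receptor chain, rose by 2.09 ± 0.094, while Klf2 and Rhob fell, at log2 -1.83 ± 0.14 and -2.33 ± 0.14. The DMSO_0h means of Cdk1, Hk2, Gins1, Exo1, Fignl1 and Il2ra lay at or below the negative-control median, so background limits the sizes of their changes. In all, limma called 7594 of 12462 genes (4202 higher, 3392 lower), of which 1841 differed at least 2-fold.

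Among the fixed lists at 18 h, 27 of 28 DNA replication genes rose (27 adjusted over the list alone), for example Mcm2 by 2.20 and Uhrf1 by 3.15 (camera adjusted p = 2.1e-14, adjusted p = 0.0461 with an estimated correlation). All 28 mitosis genes rose (28 adjusted over the list alone), with Aurkb at 3.22, but this list's call was lost with an estimated correlation (adjusted p = 6.1e-13 and adjusted p = 0.0894). Ribosome biogenesis genes rose in 24 of 26 cases (24 adjusted over the list alone; adjusted p = 8.15e-12, adjusted p = 0.0461 with an estimated correlation), Srm, which makes spermidine, by 2.91. IL-2 and STAT5 induced genes rose in 13 of 18 and fell in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.00399, adjusted p = 0.0461 with an estimated correlation), led by Socs2 at 3.38. Resting and naive T cell genes fell in 19 of 24 cases and rose in 2 (the same counts adjusted over the list alone; adjusted p = 2.64e-07, adjusted p = 0.0461 with an estimated correlation), with Klf3 at -2.74, S1pr1, the receptor for leaving lymphoid tissue, at -2.30 and Pik3ip1 at -2.07. Sterol synthesis (21 of 25 rose and 1 fell, the same adjusted over the list alone), glycolysis (14 of 20, also 14) and oxidative phosphorylation genes (23 of 25, also 23) were called with the preset correlation (adjusted p = 1.49e-05, 0.000192 and 4.63e-06) and not with an estimated one (adjusted p = 0.208, 0.148 and 0.34).

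At 48 h division genes were among the largest rises over the start, beside a chemokine and a cytotoxic gene that had risen by 18 h too (Ccl3 by 3.34 and Nkg7 by 3.16). Against the start, the chemokine gene Ccl3 rose by 5.75 ± 0.22, Cdk1 by 5.36 ± 0.21, the kinesin Kif15 by 5.16 ± 0.21, the checkpoint kinase Bub1 by 4.95 ± 0.17 and Nkg7, a cytotoxic granule gene, by 4.92 ± 0.16. Pbk, E2f8 and Gins1 rose by 4.62 to 4.80. Ramp3, Cxcr4, Klf3, Tcp11l2, Ifit1bl1, Vps37b, Pou6f1 and Rgs2 fell, at log2 -4.30, -4.27, -4.07, -3.73, -3.67, -3.58, -3.50 and -3.45. Il2ra rose by 2.32 ± 0.094, Klf2 fell by 2.29 ± 0.14 and Rhob fell by 2.63 ± 0.14. Foxp3 itself was at -0.07 ± 0.071 and did not pass the test. Background limits the sizes for Cdk1, Kif15, Bub1, E2f8, Gins1, Il2ra and, at both times, Ccl3, because their DMSO_0h means were at or below the negative-control median (4.54 against 5.64 for Ccl3), as was the DMSO_48h mean of Ifit1bl1. limma called 9311 genes (4798 higher, 4513 lower; 2576 at least 2-fold). All 28 mitosis genes rose (28 adjusted over the list alone), with a median of 3.51, and 21 of 24 resting and naive T cell genes fell and 2 rose (the same counts adjusted over the list alone), with a median of -1.1. The 11 lists called with the preset correlation included mitosis (adjusted p = 4.43e-16) and resting genes (adjusted p = 3.03e-08), and with an estimated correlation camera called 0 (adjusted p = 0.0631 for both, 10 lists at an unadjusted p under 0.05). Centring the arrays on their medians over all probe sets, controls included, moved the median gene to 0.11 at 18 h and 0.15 at 48 h, from 0 and -0.02. It turned the splits into 4834 higher and 2518 lower at 18 h and 5668 higher and 3034 lower at 48 h. These medians were 6.166 to 6.196 on the DMSO_0h arrays and 6.043 to 6.114 on the DMSO_18h arrays. Medians over gene probe sets alone were 6.158 to 6.184 and 6.14 to 6.211, so the 18 h shift came with the control probe sets. On the DMSO_48h arrays the gene medians were lower, at 6.08 to 6.101. Markers of other cells that the sort could hold were also read. At 48 h 5 of 6 red cell, 6 of 7 myeloid and dendritic and 2 of 5 B cell markers fell and 1 myeloid marker rose (the same counts adjusted over the list alone). None of these lists was called (adjusted p = 0.0648, 0.187 and 0.247). By 18 h some of these markers had fallen already, among them Cd74 (-1.27), Cd68 (-1.19), Cd79a (-0.63) and Hbb-bt (-1.41), while Cst3 had risen (0.6).

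Between 18 and 48 h in DMSO, mitosis genes, fat and sugar metabolism genes, p53 targets and cytokine genes rose. Tead1 rose by 3.26 ± 0.13, the costimulatory ligand Tnfsf4 by 2.95 ± 0.21, the fatty acid desaturase Scd1 by 2.54 ± 0.21, and Slc4a11, Fam83d, Eaf2, Prss16 and Smim3 by 2.43 to 2.64. Ms4a4b fell by 2.16 ± 0.21, Slc28a2b fell by 1.63 ± 0.21, and Cd226 and Klf3 fell, at log2 -1.34 and -1.33. All 28 mitosis genes rose (28 adjusted over the list alone; median 1.55, adjusted p = 6.48e-34, adjusted p = 0.0104 with an estimated correlation). So did 13 of 18 p53 targets (14 adjusted over the list alone, where 1 fell; adjusted p = 2.54e-07 and 0.0104), with the cell cycle inhibitor Cdkn1a at 2.41. The same holds for 9 of 13 fatty acid genes (also 9; adjusted p = 3.64e-06 and 0.0282) and 13 of 20 glycolysis genes (14; adjusted p = 8.5e-07 and 0.0367). Cytokine genes rose in 7 of 16 cases (7 adjusted over the list alone, where 1 fell; adjusted p = 0.00197 and 0.0385 with an estimated correlation), Ifng by 1.97 and Ccl4 by 2.34, and Gzmb, from the effector Treg list, rose by 2.10. Of the CD8 T and NK cell markers Nkg7 (1.77), Eomes (1.93) and Ctsw (0.89) rose too, while Cd8b1 (-0.21) did not pass the test. Resting genes fell in 16 of 24 and rose in 1 (17 and 1 adjusted over the list alone; adjusted p = 4.82e-08 and 0.0282). Treg identity genes fell in 8 of 19 and rose in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.00803 and 0.0367), Gpr83 at log2 -0.68 and Foxp3 by -0.32 ± 0.071. Since Tead1, Tnfsf4, Eaf2, Prss16, Smim3 and Ifng were not above the negative-control median at 18 h, background limits the sizes of their changes. The count was 3623 genes (2047 higher, 1576 lower), 2668 higher and 951 lower after centring on the median, and 2277 genes in all without DMSO_48h replicate 2.

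**Figure D2:**
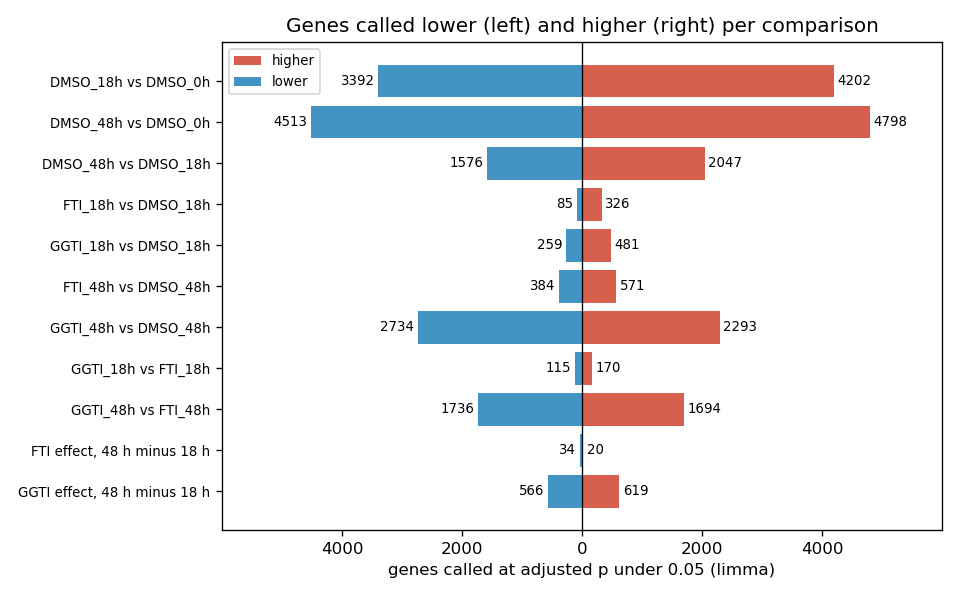
Bars give the number of genes that limma called at an adjusted p under 0.05 in each comparison, lower genes to the left of 0 and higher genes to the right, of 12462 tested. The GGTI_48h comparison with DMSO_48h shows 2734 lower and 2293 higher genes, and the FTI_48h comparison 384 and 571.

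FTI at 18 h moved few genes, and by little. Tsc22d3, a glucocorticoid-induced leucine zipper gene, rose by 1.35 ± 0.14 over DMSO_18h, Tsc22d1 by 1.14 ± 0.17, the interleukin-7 receptor gene Il7r by 1.06 ± 0.15, and Ms4a4b, Slc3a1, Slc28a2b and Cd55 by 1.01 to 1.08. The membrane semaphorin Sema7a fell by 1.14 ± 0.14, the T-box factors Eomes and Tbx21 fell, at log2 -1.11 ± 0.21 and -1.1 ± 0.27, Irf8 fell by 0.98 ± 0.15 and Ccl4 fell by 0.89 ± 0.20. Klf2 rose by 0.70 ± 0.14 and Rhob by 0.88 ± 0.14. Resting and naive T cell genes rose in 9 of 24 cases (13 adjusted over the list alone; adjusted p = 2.06e-12, adjusted p = 0.0215 with an estimated correlation), with Pik3ip1 at 1.00 and S1pr1 at 0.66. T cell cytokine genes fell in 3 of 16 (4 adjusted over the list alone; adjusted p = 0.000627, adjusted p = 0.0475 with an estimated correlation). Of 19 Treg identity genes 1 rose, Nt5e by 0.43 (3 adjusted over the list alone; adjusted p = 0.00357 and 0.0419). Replication and mitosis genes fell in 5 and 4 of 28 cases (18 and 14 adjusted over the list alone, where 1 mitosis gene rose), Nuf2 at log2 -0.68 and Pola1 at -0.43. Both list calls were lost with an estimated correlation (adjusted p = 3.63e-13 and 5.14e-11 became adjusted p = 0.0609 and 0.142). limma called 411 genes (326 higher, 85 lower), 12 of them at least 2-fold.

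That count moved with the set of arrays and genes in the fit. A fit on only the 6 arrays compared called 49 genes, a fit with no filter on dim probe sets called 183, and leaving out FTI_18h replicate 1 or 3 or DMSO_18h replicate 2 or 3 gave 151, 174, 189 and 192. Tbx21, Cd55, Ccl4, Nt5e, Nuf2, Pola1, Klf2, Ms4a4b and Slc28a2b each lost their call when at least 1 of the 6 arrays was left out. Cd55 in DMSO_18h and Eomes in FTI_18h were not above the negative-control median, so background limits both sizes.

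GGTI at 18 h raised genes of the sterol pathway and of resting T cells. Anxa2, a membrane-binding annexin, rose by 2.18 ± 0.22 over DMSO_18h, Rhob by 2.13 ± 0.15, the calcium-binding S100a6 by 1.98 ± 0.23, Cd55 by 1.90 ± 0.29, Tsc22d3 by 1.86 ± 0.15, Fads2 and Car5b by 1.77, and Adgre5 by 1.67 ± 0.13. Tbx21 fell by 2.18 ± 0.31, Plk2 fell by 1.67 ± 0.35, and Ccr8, Kit, Ly6a, A1cf and Irf8 fell, at log2 -1.27, -1.24, -1.16, -1.13 and -1.1. Sterol synthesis genes rose in 14 of 25 cases (18 adjusted over the list alone, where 1 fell; adjusted p = 2.1e-15, adjusted p = 0.0149 with an estimated correlation), among them Mvd by 0.93 and Fdft1 by 0.62. Fatty acid genes rose in 5 of 13 (9 adjusted over the list alone; adjusted p = 5.96e-07 and 0.0149). Resting genes rose in 11 of 24 (15 adjusted over the list alone; adjusted p = 3.77e-13 and 0.0149), Klf3 by 1.47 and Klf2 by 1.26. Ribosome biogenesis genes fell in 10 of 26 (21 adjusted over the list alone; adjusted p = 2.46e-14 and 0.0149), with Wdr43 at -0.57. Mitosis genes rose in 6 of 28 (8 adjusted over the list alone), Nusap1 by 1.04, a list call lost with an estimated correlation (adjusted p = 5.07e-08 became adjusted p = 0.212). limma called 740 genes (481 higher, 259 lower; 41 at least 2-fold).

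A fit on only the arrays compared called 144 genes, and a fit with no filter on dim probe sets 443. Leaving out GGTI_18h replicate 1 or 2 or DMSO_18h replicate 2 gave 201, 434 and 432, and A1cf, Ccr8, Ly6a and Plk2 each lost their call without at least 1 of the arrays. The size for Cd55 is limited by background, its DMSO_18h mean being below the negative-control median.

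With FTI at 48 h T cell cytokine genes fell and resting genes rose. Eomes fell by 3.37 ± 0.21 from DMSO_48h, Sema7a fell by 2.39 ± 0.14, Spp1 (osteopontin) fell by 2.39 ± 0.12, Ly6c1 fell by 2.36 ± 0.18, Slamf7 fell by 2.33 ± 0.16, Ly6a fell by 2.31 ± 0.22 and Ifng fell by 2.18 ± 0.16. Gzmb, the granule protease granzyme B, fell by 1.70 ± 0.25, Ccl4 at log2 -1.39 and Nkg7 by -1.14. Slc28a2b rose by 1.94 ± 0.21, Capn3 by 1.90 ± 0.16, Ms4a4b by 1.85 ± 0.21, the vasopressin receptor gene Avpr1a by 1.82 ± 0.15, Selp by 1.73, the urea transporter Slc14a1 by 1.70, the decoy receptor Il1r2 by 1.53 and Fgf2 by 1.46. Resting genes rose in 17 of 24 cases (17 adjusted over the list alone; adjusted p = 1.02e-16, adjusted p = 0.00535 with an estimated correlation), S1pr1 by 1.12 and Klf2 by 0.65. Cytokine genes fell in 8 of 16 (8 adjusted over the list alone; adjusted p = 4.41e-05 and 0.0186) and Treg identity genes rose in 5 of 19 (7 adjusted over the list alone; adjusted p = 0.00206 and 0.0186), Cst7 by 0.88. Effector Treg genes went both ways, with 3 of 26 up and 2 down (3 and 3 adjusted over the list alone; adjusted p = 0.754). Foxp3 was at -0.14 ± 0.071 and Rhob at 0.19 ± 0.14, neither past the test. limma called 955 genes (571 higher, 384 lower; 92 at least 2-fold).

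After centring on the median the split became 411 higher and 512 lower, and with array quality weights 2124 genes were called, 1060 of them higher. Without FTI_48h replicate 1 or 3 or DMSO_48h replicate 2 or 3 the count was 521, 606, 523 and 586, and the call of Cd8b1 was lost when any 1 of 5 of the 6 arrays was left out. Limited by background are the sizes for Eomes, Spp1 and Ifng, whose FTI_48h means (4.81 for Eomes) were at or below the negative-control median (5.17), and for Avpr1a and Selp, whose DMSO_48h means were.

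GGTI at 48 h gave the broadest change of the 4 inhibitor comparisons, and it ran through chemokines, resting genes, sugar metabolism and ribosome production. Ccl3 fell by 5.39 ± 0.22, Tbx21, the factor T-bet, fell by 4.33 ± 0.27, Ccl4 fell by 4.16 ± 0.20, the effector Treg receptor Ccr8 fell by 3.52 ± 0.20, and Nkg7, Slamf7, A1cf and Irf8 fell, at log2 -3.47, -3.34, -3.18 and -3.14. Ms4a4b rose by 4.50 ± 0.21, the aquaglyceroporin Aqp3 by 3.80 ± 0.13, S100a6 by 3.76 ± 0.21, Ms4a4c by 3.48 ± 0.11, Klf3 by 3.40 ± 0.14, Car5b by 3.29 ± 0.18 and the calcium channel gene Cacna1c by 3.17 ± 0.089. Rhob rose by 3.03 ± 0.14, Klf2 by 2.14 ± 0.14 and Foxp3 by 0.22 ± 0.071 (adjusted p = 0.0191, a call lost without DMSO_48h replicate 1 or 2 or GGTI_48h replicate 1 or 3). Tigit fell by 2.38 ± 0.15, Nr4a1 fell by 1.66 ± 0.27 and Ctla4 fell by 0.51 ± 0.10. Mki67 (0.24 ± 0.12), Myc (0.03 ± 0.26) and Icos (-0.05 ± 0.11) did not pass the test. The GGTI_48h means of Ccl3 (4.89), Tbx21 (5.10), Slamf7, A1cf and Ifng and the DMSO_48h mean of Ms4a4c were at or below the negative-control median (5.28 with GGTI), so background limits these sizes. limma called 5027 genes, 40.3% of those tested (2293 higher, 2734 lower; 647 at least 2-fold).

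Resting and naive T cell genes rose in 19 of 24 cases with GGTI at 48 h and fell in 3 (the same counts adjusted over the list alone; adjusted p = 8e-12, adjusted p = 0.0204 with an estimated correlation), Id3 by 2.76, Il7r by 2.53 and S1pr1 by 2.40. Ribosome biogenesis genes fell in 25 of 26 (26 adjusted over the list alone; adjusted p = 1.6e-15 and 0.0204), Utp20 at log2 -1.51 and Srm by -1.01. Glycolysis genes fell in 16 of 20 (16 adjusted over the list alone; adjusted p = 2.11e-08 and 0.025), Pfkfb3 at log2 -1.25 and Aldoa by -1.17. Cytokine genes fell in 9 of 16 and 1 rose (the same counts adjusted over the list alone; adjusted p = 0.000199 and 0.025), Ifng at log2 -2.57 and Fasl by -1.88. TCR and NF-kappaB induced genes fell in 15 of 27 and rose in 3 (16 and 3 adjusted over the list alone), Nr4a2 at log2 -2.71. This call was lost with an estimated correlation (adjusted p = 0.00574 became adjusted p = 0.605). Effector Treg genes went both ways, 8 up and 12 down (8 and 12 adjusted over the list alone; adjusted p = 0.235). Mitosis genes rose in 9 of 28 (8 adjusted over the list alone), Nusap1 by 0.87, with the list call lost under an estimated correlation (adjusted p = 0.0182 became adjusted p = 0.605). Of 28 replication genes 1 rose and 1 fell (1 and 0 adjusted over the list alone; adjusted p = 0.769).

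Some markers of other cell types moved at 48 h with GGTI, a comparison in which 40.3% of all genes were called. The alpha globin genes Hba-a1 and Hba-a2 rose by 2.06 ± 0.18 and 1.99 ± 0.19. The beta globin gene Hbb-bs was at 0.65 ± 0.56, not above the negative-control median in either group, and did not pass the test, and 2 of 6 red cell markers rose (2 adjusted over the list alone, adjusted p = 0.0653). The GGTI effect on these markers was more positive at 48 h than at 18 h for 2 of 6 (2 adjusted over the list alone; adjusted p = 0.000294, adjusted p = 0.0341 with an estimated correlation). In the list of CD8 T and NK cell markers Nkg7, Eomes and Ctsw fell and Cd8b1 rose by 0.78 ± 0.11 (3 and 1 of 5, the same counts adjusted over the list alone; adjusted p = 0.0522). Of 5 B cell markers 1 rose and 1 fell, and of 7 myeloid and dendritic markers 1 rose (the same counts adjusted over the list alone; adjusted p = 0.978 and 0.606). With FTI at 48 h 1 of 5 B cell markers and Cd8b1 rose while Eomes and Nkg7 fell (1, 1 and 2 adjusted over the list alone). Both list calls were lost with an estimated correlation (adjusted p = 0.0318 and 0.00673 became adjusted p = 0.291 and 0.0865). Among the myeloid and dendritic markers Cd74 rose with FTI at 48 h, by 0.62 ± 0.18 (limma adjusted p = 0.0377).

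**Figure D3:**
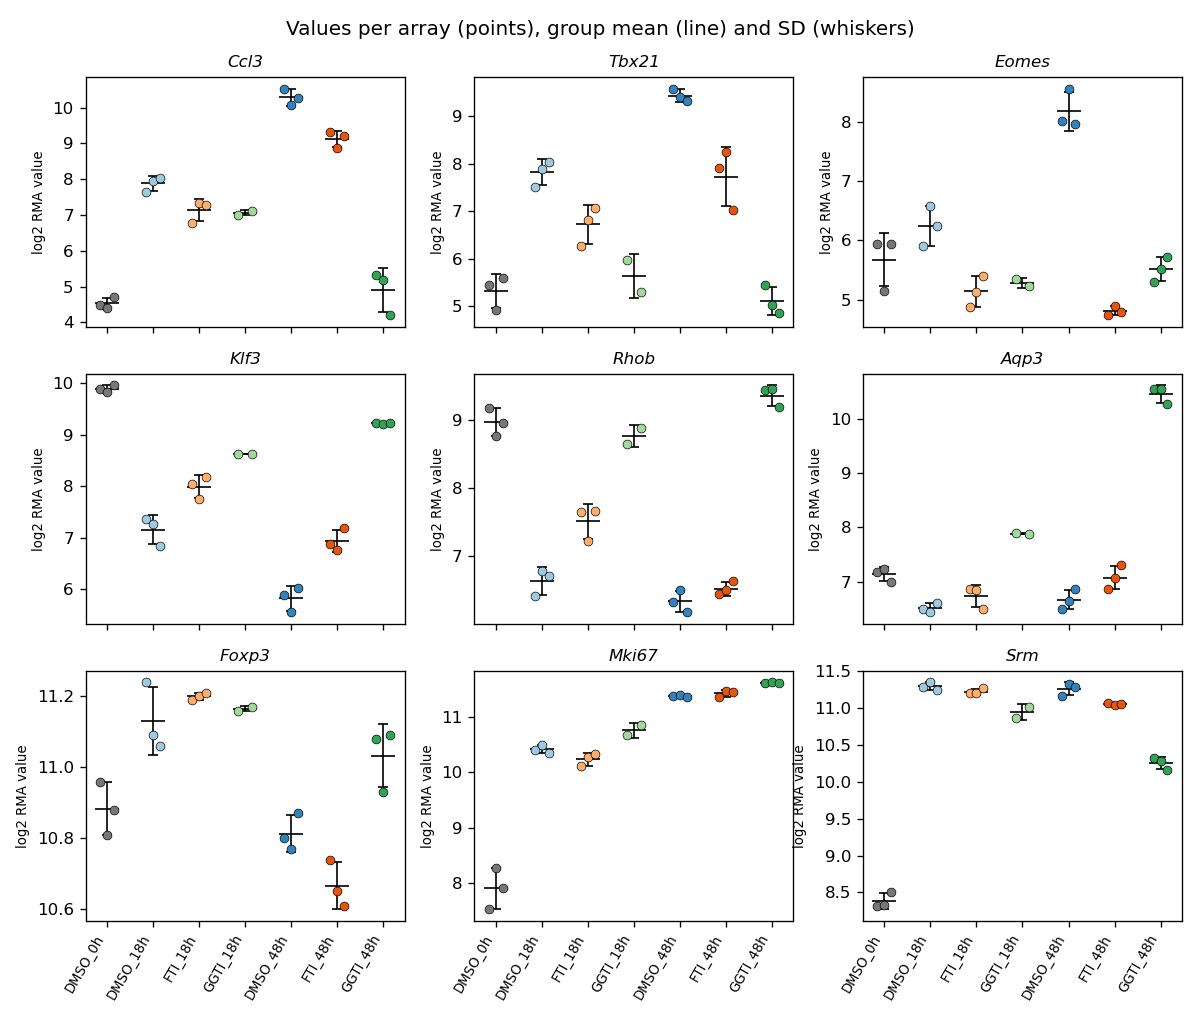
Points are log2 RMA values of single arrays for 9 genes, horizontal lines are group means and whiskers are SD, with the 7 groups along the horizontal axis (n = 3, GGTI_18h n = 2). The vertical axis of each panel has its own range. Ccl3 and Tbx21 lie lowest of the 48 h groups with GGTI, and Klf3, Rhob and Aqp3 lie highest.

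**Figure D4:**
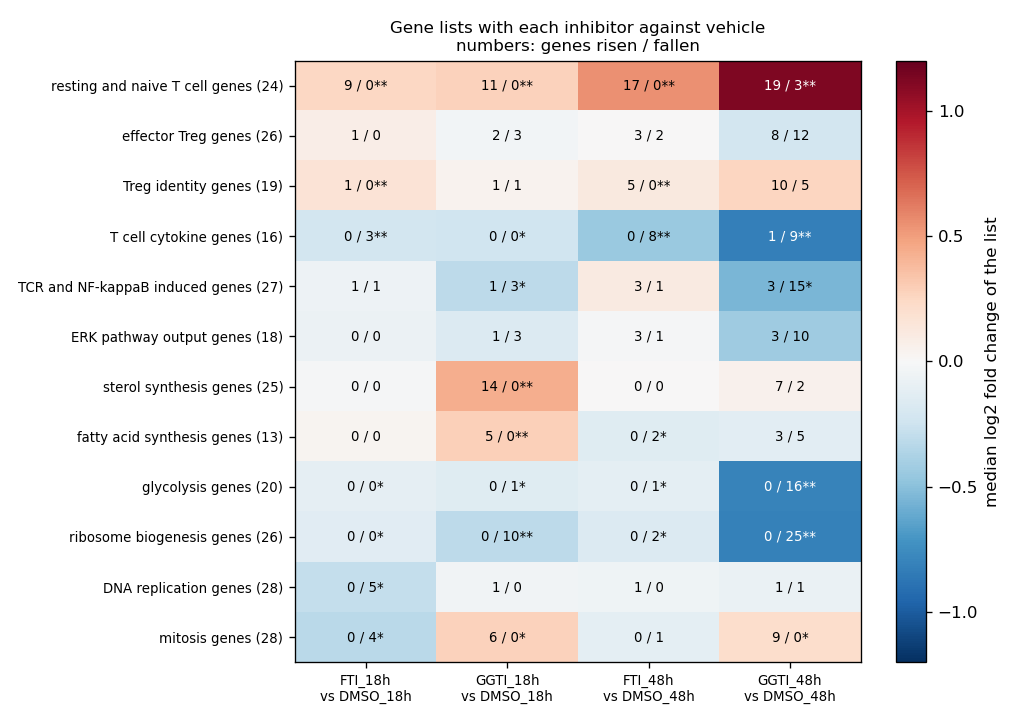
Colour gives the median log2 fold change of each fixed list against DMSO of the same time, with the number of measured genes behind the list's name and genes risen / fallen at an adjusted p under 0.05 in each cell. A single asterisk marks a camera call with the preset correlation, and a pair of asterisks a call that also holds with an estimated correlation. Ribosome biogenesis genes fell in 25 of 26 cases with GGTI at 48 h and in 2 with FTI.

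Setting GGTI directly against FTI at 18 h, sterol and mitosis genes lay higher with GGTI. Fads2 lay higher by 1.77 ± 0.27, Anxa2 by 1.59 ± 0.22, S100a6 by 1.44 ± 0.23, Emp1 by 1.36 ± 0.16, Rhob by 1.25 ± 0.15 and Aqp3 by 1.15 ± 0.14. Igsf23, Ccr8, Actg2, Slc14a1, A1cf and Npas4 lay lower, at -1.09 to -1.42. Sterol synthesis genes were higher in 12 of 25 cases (21 adjusted over the list alone, where 1 was lower; adjusted p = 4.87e-23, adjusted p = 0.00867 with an estimated correlation). Mitosis genes were higher in 14 of 28 (25 adjusted over the list alone; adjusted p = 1.61e-32 and 0.00867), and so were fatty acid genes in 2 of 13 (2 adjusted over the list alone; adjusted p = 3.99e-07 and 0.0168). limma called 285 genes (170 higher, 115 lower; 19 at least 2-fold). A fit on only the arrays compared called 106 and array quality weights 436. Without GGTI_18h replicate 1 or 2 or FTI_18h replicate 3 the count was 70, 113 and 183, and A1cf, Actg2, Ccr8 and Igsf23 each lost their call without at least 1 of them. Actg2 with GGTI was below the negative-control median, so background limits its size.

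At 48 h the inhibitors differed at 3430 genes (1694 higher with GGTI, 1736 lower; 362 at least 2-fold). Aqp3 lay higher with GGTI by 3.40 ± 0.13, Cacna1c by 3.14 ± 0.089, S100a6 by 2.95 ± 0.21, Rhob by 2.84 ± 0.14, Ifitm1 by 2.79 ± 0.16, and Tcea3, Icosl and Hepacam2 by 2.68 to 2.75. Ccl3 lay lower at -4.23 ± 0.22, and Ccr8, Npas4, A1cf, Ccl4, Tbx21, Tg and Fgf2 at -3.28, -3.23, -3.07, -2.77, -2.62, -2.60 and -2.41. Differences for Ccl3, Npas4, A1cf, Tbx21 and Fgf2 (GGTI_48h) and Tcea3 (FTI_48h) are limited by background, as the group named lay below the negative-control median. Ribosome biogenesis genes were lower in 24 of 26 (25 adjusted over the list alone; adjusted p = 6.78e-17, adjusted p = 0.0238 with an estimated correlation). Glycolysis genes were lower in 14 of 20 (15 adjusted over the list alone, where 1 was higher; adjusted p = 4.96e-09 and 0.0238). Resting genes were higher in 18 of 24 with 3 lower (the same counts adjusted over the list alone; adjusted p = 4.71e-08 and 0.0303). IL-2 and STAT5 induced genes were higher in 10 of 18 and lower in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.000627 and 0.0238), Ccnd3 by 0.56.

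Whether each inhibitor's effect differed between times was tested as an interaction. For GGTI 1185 genes passed (619 with a more positive effect at 48 h, 566 more negative; 287 by log2 1 or more). Cacna1c, Ifitm3, Ms4a4c, Aqp3 and Ifitm2 had more positive effects at 48 h, by 2.81, 2.88, 2.73, 2.43 and 2.18, and Ccl3, Ccl4, Spp1, Serpina3f and Tg more negative ones, by -4.57, -3.40, -2.28, -2.09 and -2.08. The sizes for Ms4a4c, Ccl3 and Spp1 are not exact, because at least 1 of their 4 groups lay below the negative-control median. Spp1 lay there in both GGTI groups, so whether the GGTI effect on it differed between times is not settled. Resting genes had more positive effects in 15 of 24 and more negative ones in 2 (18 and 3 adjusted over the list alone; adjusted p = 3.39e-12, adjusted p = 0.0163 with an estimated correlation). Glycolysis, cytokine and ribosome genes had more negative effects in 12 of 20, 6 of 16 and 14 of 26, with 1 cytokine gene more positive (15, 9, 18 and 1 adjusted over the list alone; adjusted p = 5.13e-11, 3.72e-05 and 4.98e-13, with an estimated correlation adjusted p = 0.0163, 0.0163 and 0.0195). The sterol list's effect was more negative at 48 h in 6 of 25 genes (13 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 7.7e-06 became adjusted p = 0.11). Without GGTI_18h replicate 2 the count was 691.

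For FTI 54 genes passed the interaction test (20 more positive, 34 more negative; 28 by log2 1 or more). Avpr1a, Cd226, Npas4, Cd53 and Ifngr2 had more positive effects at 48 h, by 1.75, 1.23, 0.84, 0.72 and 0.65, and Ly6c1, Spp1, Slamf7, Ccdc141 and Samd3 more negative ones, by -2.67, -2.33, -2.13, -1.91 and -1.28. Eomes and Ifng also had more negative effects, by -2.26 ± 0.29 and -1.84 ± 0.22. The sizes for Avpr1a, Spp1, Ccdc141, Samd3, Eomes and Ifng are not exact for the reason given for GGTI. FTI_18h was at or below that median for Avpr1a, Spp1, Samd3, Eomes and Ifng, so background may hide part of an earlier FTI effect. Whether the FTI effect on these genes differed between times is therefore not settled. Of 7 lists called with the preset correlation, 0 were called by camera with an estimated correlation, where 5 lists had an unadjusted p under 0.05. Without FTI_18h replicate 1 or 3, DMSO_48h replicate 3 or FTI_48h replicate 1 or 3 the count was 35, 35, 30, 28 and 32, and it rose to 85 with a mean trend and robust variances and to 87 with array quality weights.

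The genes that stimulation moved were then followed under each inhibitor, taking them from a comparison that shares no array with the inhibitor's. Of 7594 genes moved in DMSO by 18 h, 72.7% had a GGTI_48h effect of the opposite sign, with a mean of -0.232 ± 0.026 (SD of 3 arrays) in the direction of stimulation; raised genes averaged -0.229 and lowered genes 0.234. For FTI_48h 66.2% of them had an effect of the opposite sign, called or not, with a mean of -0.075 ± 0.007 (SD of 3 arrays). Over the 9311 genes moved in DMSO by 48 h, the mean was -0.058 ± 0.041 (SD of 3 arrays) for FTI_18h, with 62.2% of opposite sign. For GGTI_18h it was -0.077 ± 0.048 (SD of 2 arrays), with 67.3% of opposite sign. These SDs leave out the spread of the DMSO arrays, whose SD was 0.048 at 18 h and 0.023 at 48 h. Taking only stimulation genes of at least 2-fold, the means were -0.14 for FTI_18h, -0.139 for GGTI_18h, -0.131 for FTI_48h and -0.403 for GGTI_48h. Exact 2-sided permutation tests of the arrays' means gave p = 0.1 for both 48 h comparisons and p = 0.3 for both 18 h comparisons, and 0.1 is the smallest p these group sizes allow. These shares are across genes, which are not independent replicates.

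Both inhibitors were compared with the same DMSO arrays at each time. At 48 h, 762 genes were called for both in the same direction (458 higher, 304 lower) and 32 in opposite directions. Independent lists of these sizes would share 189 and unchanged groups simulated against the same controls shared 0 in each of 100 draws. Their log2 fold changes correlated at r = 0.633 across genes (0.501 simulated), with a covariance of 0.0767 against 0.00725 simulated, a difference of 0.0695. At 18 h the same-direction count was 187 (165 higher, 22 lower; 5 opposite; 14.3 for independent lists, 0 simulated), with r = 0.558 (0.445 simulated) and a covariance of 0.0237 against 0.00719, a difference of 0.0165. The 3 control arrays per time were too few to split with at least 2 in each part, so part of the excess of these counts over independent lists may come from the shared controls. The simulated count of 0 does not exclude this, because the simulated groups held no changed genes and so hardly any calls to share. The pairs with no shared control gave 314 genes for FTI_18h with GGTI_48h (267 higher, 47 lower; 78.6 for independent lists, r = 0.473, -0.002 simulated) and 219 for FTI_48h with GGTI_18h (163 higher, 56 lower; 30.0 for independent lists, r = 0.402, -0.001 simulated).

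The counts shared by both inhibitors followed single arrays as the lists themselves did. At 18 h the count of 187 became 86, 102, 81, 91, 75 and 106 without DMSO_18h replicate 2 or 3, FTI_18h replicate 1 or 3 and GGTI_18h replicate 1 or 2. At 48 h the count of 762 became 442, 497, 448 and 492 without DMSO_48h replicate 2 or 3 and FTI_48h replicate 1 or 3, and 1687 with array quality weights. The 314 genes of FTI_18h with GGTI_48h became 145, 155, 121 and 141 without DMSO_18h replicate 2 or 3 and FTI_18h replicate 1 or 3, and the 219 of FTI_48h with GGTI_18h became 141 and 79 without DMSO_48h replicate 2 and GGTI_18h replicate 1.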

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

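The tests on mitosis genes, on globin genes and on Cd8b1 and Foxp3, and the relabelling after removal of the mean FTI effect, were chosen after the result was seen, while the relabelling and split tests were fixed before it.

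The effects of both inhibitors differed between 18 h and 48 h by an interaction test, which is what singled out the values of this part. For FTI 54 genes passed, led by Avpr1a (1.75), Cd226 (1.23), Npas4 (0.84), Cd53 (0.72) and Ifngr2 (0.65) with more positive effects at 48 h and by Ly6c1 (-2.67), Spp1 (-2.33), Slamf7 (-2.13), Ccdc141 (-1.91) and Samd3 (-1.28) with more negative ones, as log2 differences. For GGTI 1185 genes passed, led by Ifitm3 (2.88), Cacna1c (2.81), Ms4a4c (2.73), Aqp3 (2.43) and Ifitm2 (2.18) and by Ccl3 (-4.57), Ccl4 (-3.40), Spp1 (-2.28), Serpina3f (-2.09) and Tg (-2.08). The sizes for Avpr1a, Spp1, Ccdc141, Samd3, Ms4a4c and Ccl3 are not exact, because at least 1 of their 4 groups lay at or below the negative-control median. FTI_18h was there for Avpr1a, Spp1 and Samd3, as was GGTI_18h for Spp1, so background may hide part of an effect at 18 h. Whether those effects differed between times is not settled. Groups of 2 or 3 arrays are too small for a test of single arrays that stand apart.

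Relabelling FTI and DMSO arrays within each time called at least 54 genes in 14 of 100 draws, the real labels among them, and up to 687. This points to a structure of the samples: 13 of the 24 draws that kept or mirrored the true labels at 1 time reached 54, against 0 of the 75 draws mixed at both times, where the highest was 2. That structure is the FTI effect common to both times. Once the mean FTI effect of both times was subtracted, 1 of 100 draws, the real labels, reached 54 and the highest other called 1. The subtraction used the true labels and left any difference between times in the FTI arrays. Such a difference adds to the spread of the mixed draws and lowers their calls. Their low counts thus do not measure the calls that arise without a difference.

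For the comparisons of 3 with 3 arrays, 10 splits are too few for a share under 0.05. In each, 1 of 10 splits, the real one, called as many genes. The other splits put arrays of both groups together, so a true difference adds to their spread and lowers their calls. Low counts in those splits are therefore no measure of the calls that arise without a difference. The real values and the highest other were 7594 and 0 for DMSO_18h against DMSO_0h, 9311 and 0 for DMSO_48h against DMSO_0h, 3623 and 0 for DMSO_48h against DMSO_18h, 411 and 1 for FTI_18h and 955 and 1 for FTI_48h against DMSO, 5027 and 0 for GGTI_48h against DMSO_48h, and 3430 and 0 for GGTI_48h against FTI_48h.

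With GGTI at 48 h many stimulation genes moved back towards their starting values, while mitosis genes did not fall. Cells that stayed unstimulated would carry low mitosis genes, but their median GGTI effect was 0.21, beside -0.81 for ribosome biogenesis genes, and the lowest GGTI array still lay 0.14 above the DMSO mean on the log2 scale. Stimulation that ran later would also leave mitosis genes lower, since all 28 rose from 18 to 48 h in DMSO, but 23 of 28 lay above DMSO with GGTI. The mitosis genes thus argue against unstimulated cells and against a delay of the whole program. Many glycolysis, p53 target and cytokine genes also rose from 18 to 48 h in DMSO. With GGTI at 48 h many genes of these lists lay lower than in DMSO, as a delay could leave them. The cytokine gene Ccl3 was different, at 7.01 and 7.11 on the GGTI_18h arrays and 4.19 to 5.32 on the GGTI_48h arrays. It thus lay below its own 18 h values, which a delay alone would not give. Fatty acid genes, which had risen too, went both ways. A delay of parts of the program and a direct effect of the inhibitor on parts of it both stay open.

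With GGTI at 48 h the alpha globin genes Hba-a1 and Hba-a2 rose. RNA of red cells would bring alpha and beta globin together. On the DMSO_0h arrays alpha globin lay at 6.84 to 7.32 and beta globin at 6.48 to 7.97, while on the GGTI_48h arrays alpha globin reached 7.92 to 8.20 and beta globin only 4.62 to 6.07, on the log2 scale. The mean beta level was thus lower by 1.72 ± 0.61 (SE), which argues against red cells. Binding of other transcripts to the alpha globin probes and a change within the Treg cells both stay open.

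With both inhibitors at 48 h Tbx21, Eomes, Nkg7, Ccl3 and Ccl4 lay lower, genes that CD8 T cells and conventional CD4 cells also express. Fewer CD8 T cells would lower Cd8b1, which instead lay higher by a mean of 0.58 ± 0.09 (SE) over both inhibitors, while Cd8a was at -0.34 (adjusted p = 0.429) with FTI and -0.17 (adjusted p = 0.621) with GGTI. That mean joins 0.78 with GGTI and 0.38 with FTI, whose call was lost without single arrays. Cd8b1 had also fallen with stimulation, at -0.49 in DMSO_48h against DMSO_0h, and many stimulation genes moved back with GGTI. Its rise therefore cannot decide whether CD8 T cells were fewer. Fewer CD4 cells without Foxp3 would raise Foxp3, whose mean change of 0.04 ± 0.06 joins -0.14 with FTI (adjusted p = 0.252) and 0.22 with GGTI (adjusted p = 0.0191), a call lost without 1 of several arrays, so Foxp3 moved that way with GGTI only and the explanation stays open. The sort on the Foxp3 reporter selects against such cells, and an effect of the inhibitors within the Treg cells stays open.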

How the results depend on the processing

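No paired analysis was possible because the labels give no replicate numbers that link arrays of different groups, and the numbers used here are only their order. A group of 2 arrays is left with 1 when the other is taken out, and that array is then assumed to vary like the other groups. Signal over background limits dim genes, and the filter decides which of them are tested. Leaving out DMSO_18h replicate 3 and DMSO_0h replicate 2 together, chosen after seeing the data, gave 7395, 9292 and 3334 genes for the comparisons within DMSO in the order of the report, 307 for FTI_18h and 795 for GGTI_18h.

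Of the 253 gene values named for a comparison, none that passed the test changed direction under the alternatives that measured it. The stricter filter left 19 of these values unmeasured. Leaving out 1 array did so for Actg2 (GGTI against FTI at 18 h, without FTI_18h replicate 1) and Samd3 (FTI interaction, without DMSO_48h replicate 1 or 2). The fit on only the arrays compared and the 2-fold threshold were run for counts and not for single genes. Those that changed sign had not passed: Foxp3 at 48 h against the start (0.10 when median centred, which lifts the median gene of that comparison by construction), and with GGTI at 48 h Myc (-0.02 when median centred, 0 to 0.06 without 1 array), Fnta (0 when median centred, -0.04 to 0.11 without 1 array) and Icos (-0.09 to 0 without 1 array). Lists near no change with GGTI at 48 h also changed direction. Their adjusted p were 0.898 with no filter and 0.939 when quantile normalized again for B cell markers, and 0.723 with the stricter filter, 0.926 when quantile normalized again and 0.892 with array weights for SRF and actin genes. Without 1 array they ran from 0.804 to 0.994 for B cell markers, 0.767 to 0.994 for SRF and actin, 0.778 to 0.994 for NRF2 target and 0.626 to 0.994 for DNA replication genes. The cause was not tested.

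The 2-fold threshold leaves fewer genes by construction: 1841, 2576, 297, 12, 41, 92, 647, 19, 362, 28 and 287 for the comparisons in the order DMSO_18h and DMSO_48h against DMSO_0h, DMSO_48h against DMSO_18h, FTI_18h, GGTI_18h, FTI_48h and GGTI_48h against DMSO, GGTI against FTI at 18 and 48 h, and the FTI and GGTI interactions. Shared calls became 6 at 18 h, 69 at 48 h, 12 for FTI_18h with GGTI_48h and 9 for FTI_48h with GGTI_18h. With stimulation genes of at least 2-fold the signed means were -0.14, -0.139, -0.131 and -0.403 for FTI_18h, GGTI_18h, FTI_48h and GGTI_48h, and the shares of opposite sign 76.4% (FTI_18h), 75.3% (FTI_48h) and 77.9% (GGTI_48h).

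With no filter on dim probe sets, more genes are tested and FTI_18h gave 183, GGTI_18h 443, and the shared calls were 88 at 18 h, 149 for FTI_18h with GGTI_48h and 123 for FTI_48h with GGTI_18h. With only the arrays compared, fewer arrays estimate the spread and FTI_18h gave 49, GGTI_18h 144 and GGTI against FTI at 18 h 106. Array quality weights gave 2124 for FTI_48h, 436 for GGTI against FTI at 18 h, 87 for the FTI interaction and 1687 shared calls at 48 h, and trend and robust variances gave 85 for the FTI interaction; the cause was not tested. The FTI_48h share of opposite sign was 67.0% with the stricter filter, 64.1% when quantile normalized again, 68.0% when median centred and 67.1% with array weights; the cause was not tested.

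With an estimated correlation, camera called 4 lists at 18 h and 0 at 48 h against the start, 7 between 18 and 48 h, 3 for FTI_18h, 4 for GGTI_18h, 3 for FTI_48h, 4 for GGTI_48h, 3 and 4 for GGTI against FTI at 18 and 48 h, and 0 and 7 for the FTI and GGTI interactions. The 48 h count of 0 against the start goes with 10 lists at an unadjusted p under 0.05, and the FTI interaction's with 5. The stricter filter, with fewer genes per list, called 8 lists between 18 and 48 h and 11 for the GGTI interaction.

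Leaving out 1 array at a time, with fewer arrays, gave 2277 to 3675 genes for DMSO_48h against DMSO_18h, 151 to 428 for FTI_18h, 201 to 710 for GGTI_18h, 521 to 767 for FTI_48h, 70 to 208 for GGTI against FTI at 18 h, 28 to 61 for the FTI interaction and 691 to 1236 for the GGTI interaction. It gave 75 to 207 shared calls at 18 h, 442 to 698 at 48 h, 121 to 324 for FTI_18h with GGTI_48h and 79 to 209 for FTI_48h with GGTI_18h. Shares of opposite sign were 58.9% to 70.6% for GGTI_18h and 63.6% to 67.7% for FTI_48h. Lists called were 7 to 12 for FTI_18h, 8 to 14 for FTI_48h and 7 to 11 for GGTI against FTI at 18 h.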

Other observations

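No tests were chosen after the result was seen in this part, but Ifitm1, Ifitm2 and Ifitm3 were named after their values were seen. With GGTI at 48 h, interferon response genes moved both ways: 9 of 16 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0795). The RNA sensor Ddx58 rose by 1.91 ± 0.19 and Gbp3 by 1.32 ± 0.11, while the tetherin gene Bst2 fell by 1.23 ± 0.14. Ifitm1, Ifitm2 and Ifitm3, membrane proteins that restrict viral entry, rose by 2.81, 1.99 and 2.78 on the log2 scale. Amino acid transporter genes fell in 7 of 10 cases and rose in 1 (the same counts adjusted over the list alone), Slc7a5 and Slc3a2, which pair as a leucine transporter, by log2 -0.99 and -0.78. ATF4 stress genes fell in 12 of 18 and rose in 3 (the same counts adjusted over the list alone), with Asns at -1.59, Atf3 at -2.17 and Trib3, which rose, at 1.76. Heat shock genes fell in 6 of 13 (6 adjusted over the list alone), Hspd1 by log2 -1.37, and oxidative phosphorylation genes in 10 of 25 (10 adjusted over the list alone). All 4 calls were lost with an estimated correlation (adjusted p = 0.0138, 0.0257, 0.0182 and 0.0138 became adjusted p = 0.242, 0.125, 0.242 and 0.605). IL-2 and STAT5 induced genes rose in 11 of 18 and fell in 4 (the same counts adjusted over the list alone), also lost (adjusted p = 0.0461 became adjusted p = 0.125).

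Ras and Rap family genes, and genes downstream of them, went both ways with GGTI at 48 h. Of 16 Ras and Rap family genes 4 rose and 4 fell (the same counts adjusted over the list alone; adjusted p = 0.433), Rras by 1.42 and Rras2 by 1.22 among those that rose. ERK pathway output genes fell in 10 of 18 and rose in 3 (the same counts adjusted over the list alone; adjusted p = 0.119), with the phosphatase Dusp4 at -1.46, Etv5 at -1.30 and Emp1, which rose, at 1.80. SRF and actin cytoskeleton genes rose in 6 and fell in 5 of 24 (the same counts adjusted over the list alone; adjusted p = 0.987), with Cnn3 at -1.65, Egr1 at -1.85 and Mrtfa at 0.76. Of 14 prenylation machinery genes 2 rose and 4 fell (2 and 5 adjusted over the list alone; adjusted p = 0.241), Rabggtb, a subunit of the Rab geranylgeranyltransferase, by log2 -0.92. The transferase subunit genes Fntb (-0.07 ± 0.16) and Fnta (0.05 ± 0.13) did not pass the test, and Pggt1b was at -0.31 ± 0.12 (adjusted p = 0.0418), a call lost without DMSO_48h replicate 2 or 3 or GGTI_48h replicate 1. p53 target genes fell in 11 of 18 and rose in 3 (11 and 5 adjusted over the list alone; adjusted p = 0.0896), with Perp at -1.54, Pmaip1 at 1.34 and Sesn1 at 1.00. Among 16 BCL2 family genes 3 rose, Bcl2l11 by 0.92 and Bcl2 by 0.87 among them, and 6 fell (the same counts adjusted over the list alone; adjusted p = 0.684). Lysosome and autophagy genes rose in 6 of 19 and fell in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0896). Of 9 NRF2 targets 1 rose, Gclc by 1.02, and 1 fell (the same counts adjusted over the list alone; adjusted p = 0.973). Treg identity genes rose in 10 of 19 and fell in 5 (the same counts adjusted over the list alone; adjusted p = 0.0653). Sterol synthesis genes rose in 7 of 25 and fell in 2, Mvd by 0.89 among those that rose, and fatty acid synthesis genes rose in 3 of 13 and fell in 5, Scd1 by log2 -1.14 (the same counts adjusted over the list alone; adjusted p = 0.391 and 0.684).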
